A study of Mus musculus with 6 samples.

How the data were processed

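Gastrocnemius RNA of WT and lnc-ORA KO mice was sequenced by the authors in 3 libraries per genotype after mRNA fragmentation and random-primed cDNA synthesis, per the labels' protocols. Genotype and replicate number came from the sample titles. The submitters' processing notes name the genome build GRCm39; the aligner, the counting program, the annotation release and strand handling are not given in the sources used here. Everything below starts from the authors' deposited table of 11815 genes.

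The authors deposited RPKM values per gene and library; the header names no unit, and RPKM was inferred from the values. Multiplying each value by a gene length and a library total gave whole reads in all 6 libraries for 99.7% of genes (11783, within 0.02 of a whole read), with totals of 54370181 to 69693905 reads. The median gene had 295 reads in its lowest library. Lengths from GENCODE M21 gave whole reads for 80.3% of the 11502 genes with a symbol there, and other lengths were inferred from the values. The authors' log2 fold change and log2 CPM columns, their F score and their p-value and FDR columns are named as such per the file headers; the test behind them is not given in the sources used here. 17 symbols in the deposited table look like dates, as a spreadsheet program makes them. All value columns were mapped to a sample or to the authors' comparison.

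Because the deposited values are RPKM and not counts, the test written before the data were examined for that case was used. It was limma-trend with empirical Bayes moderation (limma 3.58.1, R 4.3.3) on log2(RPKM + 1), for genes of at least 1 RPKM in at least 3 libraries, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and SDs are of RPKM. 35 gene lists were fixed before the data were examined. Lists with at least 5 tested members (28) were tested with limma's camera at a preset correlation of 0.01, and the list of Y-linked genes and Xist served only as a check. This test compares the members of a list with all other tested genes, so a list can pass as higher with a median near 0. Adjusted p of named genes and lists come from these limma fits unless another test is named.

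Named genes followed a rule fixed before the data were examined: Myh1, Myh2, Myh4, Myh7 and Ppargc1a; the 10 largest changes each way among called genes whose groups did not overlap and whose mean lay in the upper 75% of tested genes; up to 4 called members of each list with the largest changes, or the member with the smallest p where none was called; and for lists that passed, up to 4 members with the smallest p. From these, examples are given per list, and genes named outside the rule (Actg1, Plac9a, Ucp3, Cnp, Eif2s3y and the pseudogene copies) were chosen after their values were seen. Genes at the targeted locus were part of the rule and were not analysed here. Some genes that the rule took are not reported here. Overlaps and shared 50-base stretches came from the GENCODE M21 annotation and transcripts (GRCm38), which is not the build of the notes, so coordinates are of GRCm38 only.

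The fit was tested on simulated data made from the real means, with 200 of 7532 tested genes changed. It made 162 calls, of which 4.32% were false, and recovered 49.2% of genes changed 1.5-fold, 93.8% of those changed 2-fold and 98.4% of those changed 4-fold. The simulated genes varied independently of each other, and as many were raised as lowered. The real calls were mostly lower, so the simulation does not give the share of false calls in the real data.

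Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, equal library medians, a fold threshold, an unadjusted p, each replicate left out, replicate number as a block, and for lists an estimated correlation and limma's fry. Chosen after the data were seen were limma-voom on the recovered reads, library totals without the 10 most abundant genes, and protein-coding genes only. The alternatives planned for a deposited count table were not run on the recovered reads. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 did the remaining sums, and matplotlib 3.10.9 the figures.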

Results

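RNA of the gastrocnemius, a calf muscle made mostly of fast fibres, was sequenced from mice that lack the long non-coding RNA lnc-ORA and from wild-type (WT) mice. The knockout (KO) animals carried a CRISPR deletion of 5147 bp on a C57BL/6 background, and the muscle was taken at 15 weeks of age. The study asked what lnc-ORA does in the conversion of muscle fibre types. There were 3 WT libraries (replicates 2, 3 and 4) and 3 KO libraries (replicates 1, 2 and 3). The counted reads came to 69693905, 54370181 and 65533717 in WT replicates 2, 3 and 4 and to 68718183, 55607994 and 61142098 in KO replicates 1, 2 and 3. Values were RPKM for 11815 genes, of which 7574 reached 1 RPKM in at least 3 libraries and were tested. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 25.2 between KO libraries and at least 80.1 between WT libraries. The labels do not say whether each library came from its own animal, so the p-values measure only the spread between these libraries. The Y-linked genes Ddx3y and Eif2s3y, the tested members of the list of Y-linked genes and Xist, were not called. Ddx3y stood at 5.98 ± 1.57 RPKM in WT and 5.26 ± 1.07 in KO (SD, n = 3 each).

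The deleted locus and the level of lnc-ORA were not analysed here, because the genome sequence needed to place the guides was not used here. The genotype labels were therefore taken as given.

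The fast myosin genes of the less glycolytic fibres were lower in KO muscle. Myh1, the myosin heavy chain of type IIx fibres, stood at 2432 ± 678 RPKM in WT and 1135 ± 299 in KO (SD, n = 3 each), a log2 fold change of -1.09 (SE 0.25, adjusted p = 0.0225). Myh2, the myosin of type IIa fibres, went from 1621 ± 168 to 896 ± 308 RPKM (log2 fold change -0.90, SE 0.21, adjusted p = 0.0261). Myh4, the myosin of type IIb fibres, took the largest share of the reads of any gene. It was at 33597 ± 2395 RPKM in WT and 41345 ± 651 in KO, a log2 fold change of 0.30 that did not pass (adjusted p = 0.0885). Myh7, the slow myosin, varied from 30.9 to 269 RPKM among the WT libraries and stood at 94.8 ± 22.6 in KO, with no difference beyond that spread (adjusted p = 0.914). Myh2, Myh1 and Myh4 lie side by side on chromosome 11 (67171027 to 67260446, GRCm38) and share sequence: 32.1% of the 50-base stretches of the longest Myh1 transcript and 28.9% of those of Myh2 also occur in transcripts of other genes. The calls of Myh1 and Myh2 ended without WT replicate 2 or 3 or KO replicate 1 or 3, with adjusted p of up to 0.0885 and 0.102, both without KO replicate 3.

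Of 16 tested fast-fibre contractile genes, 3 fell (3 adjusted over the list alone) and none rose. Besides Myh1 and Myh2 this was Mylk2, the skeletal myosin light chain kinase, at 204 ± 36.0 RPKM in WT and 133 ± 7.31 in KO. The list did not pass as a set (adjusted p = 0.0991 with camera), and its median log2 fold change of 0.05 and its mean of -0.05 differed in sign. Of 14 slow-fibre contractile genes, 2 fell (1 adjusted over the list alone): Csrp3, a Z-disc protein, from 23.2 ± 9.46 to 7.31 ± 3.29 RPKM, and Ankrd2, a stretch-responsive protein, from 250 ± 120 to 97.4 ± 41.1 RPKM. This list did not pass either (adjusted p = 0.552). Without WT replicate 3 the slow list passed as lower (adjusted p = 0.000253) and the fast list as higher (adjusted p = 0.00791). Mylk2 lost its call without WT replicate 3 or any KO replicate (adjusted p of up to 0.0814), Csrp3 without KO replicate 1 or 3 (up to 0.067), and Ankrd2 without WT replicate 2 or 4 or KO replicate 1 or 3 (up to 0.15).

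**Figure D1:**
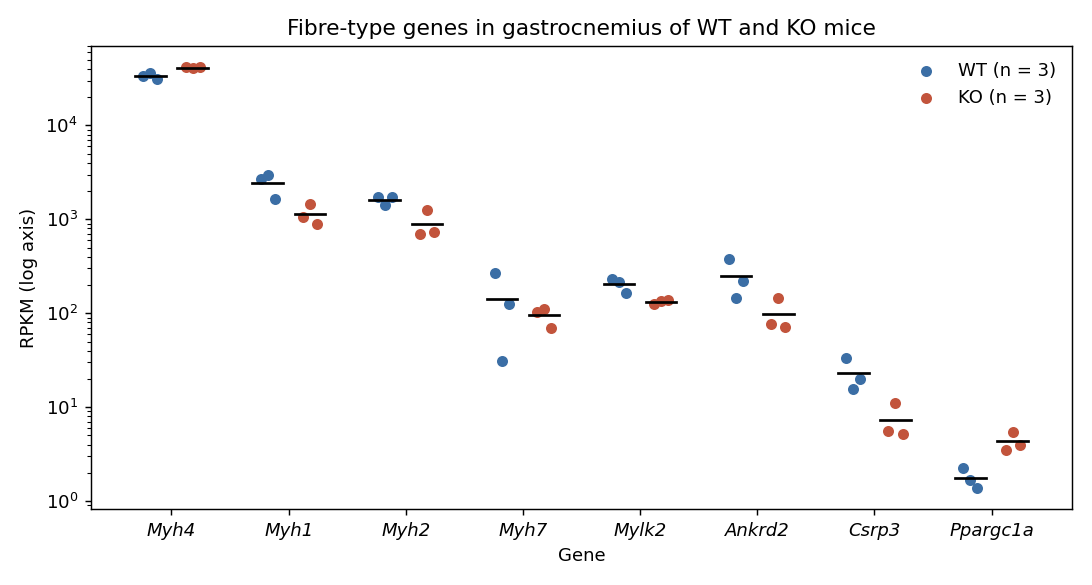
RPKM (log axis) of 8 genes tied to fibre type in each of the 3 WT and 3 KO gastrocnemius libraries; points are libraries and bars group means. Myh1 and Myh2 lie lower in every KO library than in every WT library, Ppargc1a lies higher, and the WT libraries of Myh7 spread from 30.9 to 269 RPKM.

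Regulators of fibre type moved in both directions. Of 25 tested, 6 rose and 4 fell (7 and 6 adjusted over the list alone). Ppargc1a, the coactivator that drives mitochondrial genes, went from 1.77 ± 0.45 to 4.34 ± 1.03 RPKM (log2 fold change 0.94, SE 0.16, adjusted p = 0.0082). The large Maf factors Maf (0.72) and Mafa (0.68) and the nuclear receptors Nr4a1 (0.69) and Nr4a3 (0.73) also rose on the log2 scale. Vgll2, a cofactor of TEAD factors, went from 9.67 ± 2.09 to 4.81 ± 0.733 RPKM (log2 fold change -0.87). As a set the list passed as higher than the other tested genes (adjusted p = 0.0197 with camera). Its median log2 fold change was 0.04, with 15 members above 0 and 10 below. It did not pass with an estimated correlation (adjusted p = 0.917) or with library medians made equal (adjusted p = 0.131). It did not pass either with no filter on low values (adjusted p = 0.0969), in limma-voom (adjusted p = 0.14) or with totals without the 10 most abundant genes (adjusted p = 0.142).

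Genes of fatty acid uptake and oxidation were lower in KO muscle. Of 29 tested, 19 fell and 1 rose, the uncoupling protein Ucp3 (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.47. Acot2, a mitochondrial acyl-CoA thioesterase, went from 8.12 ± 3.03 to 2.55 ± 0.709 RPKM, and the fatty acid transporter Slc27a1 from 4.40 ± 0.781 to 1.95 ± 0.333. The long-chain dehydrogenase Acadl went from 112 ± 19.6 to 61.0 ± 6.13 RPKM and the very-long-chain dehydrogenase Acadvl from 66.8 ± 6.23 to 43.9 ± 3.72. The list passed as lower (camera adjusted p = 1.5e-05), but not with an estimated correlation (adjusted p = 0.917).

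Of 40 tested genes of oxidative phosphorylation complexes II to V, 4 fell (4 adjusted over the list alone), with log2 fold changes from -0.34 for Uqcrq to -0.30 for Atp5l. All 4 calls, with Cox6b1 (-0.32) and Uqcrc2 (-0.31), ended with library medians made equal (adjusted p of 0.0986 to 0.126). They also ended without KO replicate 1, 2 or 3, without WT replicate 2 for Uqcrq and Atp5l, and without WT replicate 3 for Cox6b1, Uqcrc2 and Atp5l (adjusted p of up to 0.138). The set passed as lower (adjusted p = 0.0205), but not with an estimated correlation (adjusted p = 0.917) or with library medians made equal (adjusted p = 0.138). Nor did it pass without WT replicate 4 (adjusted p = 0.53) or KO replicate 2 (adjusted p = 0.0748), with a pseudocount of 0.1 (adjusted p = 0.0791), in limma-voom (adjusted p = 0.0713) or with totals without the 10 most abundant genes (adjusted p = 0.558). With replicate number as a block the set did not pass either (adjusted p = 0.401). No member passed in limma among 36 genes of complex I (set adjusted p = 0.279) or among 21 genes of the tricarboxylic acid cycle (set adjusted p = 0.347), and none did adjusted over the list alone. At an unadjusted p under 0.05, 7 and 6 of them were lower and none higher. Without WT replicate 2 the complex I set passed as lower (adjusted p = 0.014).

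Glycolysis and glycogen genes went both ways, 4 up and 4 down of 29 (5 and 5 adjusted over the list alone), and the set did not pass (adjusted p = 0.441). Pfkfb3, which makes the activator of phosphofructokinase, went from 26.8 ± 8.23 RPKM in WT to 3.84 ± 0.633 in KO, a log2 fold change of -2.49 (SE 0.21, adjusted p = 0.00104). The glycogen branching enzyme Gbe1 (-1.03) and the muscle fructose bisphosphatase Fbp2 (-0.73) fell as well, while the glycerol phosphate dehydrogenase Gpd1 rose from 37.3 ± 2.31 to 60.5 ± 2.78 RPKM. Outside the lists, Ppp1r3c, which targets protein phosphatase to glycogen, rose from 110 ± 25.5 to 362 ± 21.6 RPKM (log2 fold change 1.73, SE 0.17, adjusted p = 0.00136). Among 17 genes of mitochondrial biogenesis and dynamics, 1 rose, Ppargc1a, and 1 fell, the mitophagy receptor Bnip3 (1 and 0 adjusted over the list alone), and the set did not pass (adjusted p = 0.972). Bnip3 lost its call without WT replicate 2 or 3 or KO replicate 1, 2 or 3 (adjusted p of up to 0.148). Of 10 lipid synthesis genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; set adjusted p = 0.972).

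**Figure D2:**
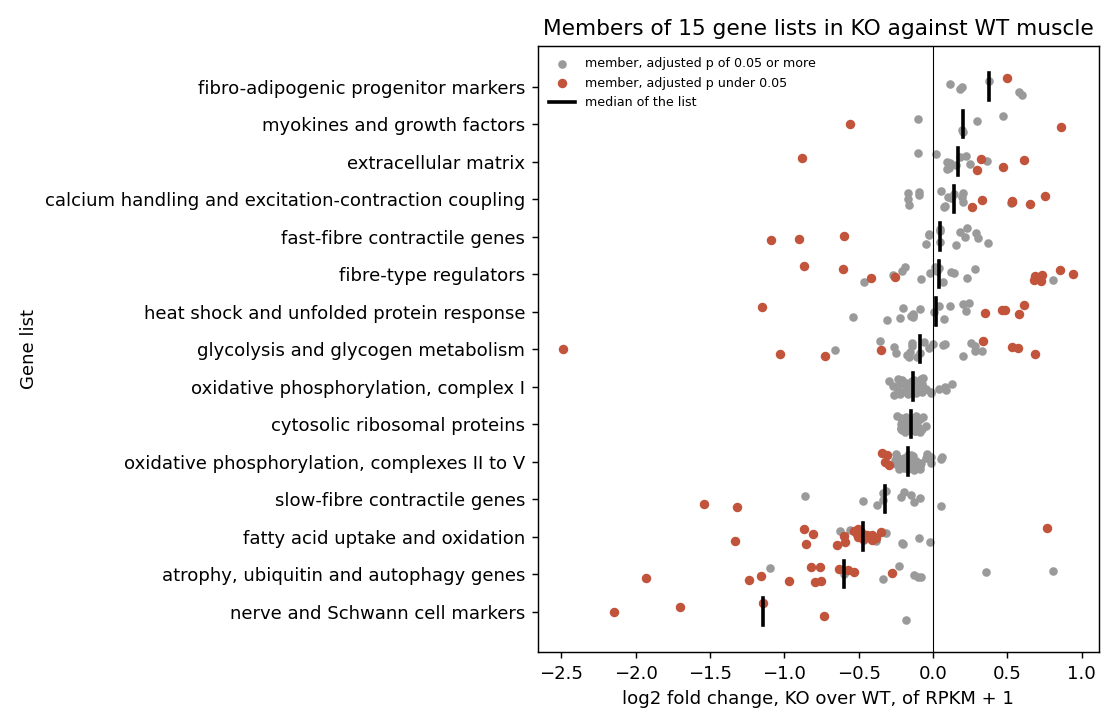
Log2 fold change of RPKM + 1, KO over WT, for each tested member of 15 gene lists; coloured points passed adjusted p 0.05 and black bars are list medians. Nerve, atrophy and fatty acid lists have the lowest medians, at -1.14, -0.60 and -0.47.

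Genes of muscle atrophy, ubiquitin conjugation and autophagy were lower in KO muscle. Of 21 tested, 12 fell and none rose (13 and 1 adjusted over the list alone). Fbxo32, the muscle ubiquitin ligase atrogin-1, went from 219 ± 76.8 to 55.3 ± 13.5 RPKM (log2 fold change -1.93, SE 0.28, adjusted p = 0.00547). Eif4ebp1, a repressor of translation, went from 20.1 ± 6.77 to 7.70 ± 1.36 RPKM and the autophagy kinase Ulk1 from 3.65 ± 0.977 to 1.60 ± 0.13. The set passed as lower (adjusted p = 0.00651), but not with an estimated correlation (adjusted p = 0.917) or in limma-voom (adjusted p = 0.0632). Whole reads were not recovered for Fbxo32, so the limma-voom fit and its set test ran without it.

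Several calcium handling and excitation-contraction coupling genes were higher in KO muscle. Of 21 tested, 6 rose and none fell (7 and 0 adjusted over the list alone). Jph2, which holds the triad membranes together, went from 25.8 ± 2.97 to 44.1 ± 3.25 RPKM, the calmodulin gene Calm3 from 72.5 ± 7.47 to 105 ± 1.66 and the kinase Camk2a from 16.9 ± 2.05 to 24.7 ± 0.56. The set passed as higher (adjusted p = 1.5e-05), with a median log2 fold change of 0.14, 16 members above 0 and 5 below. It did not pass with an estimated correlation (adjusted p = 0.84) or by fry's directional test (adjusted p = 0.0835). Camk2a lost its call without KO replicate 3 (adjusted p = 0.0573). Of 22 heat shock and unfolded protein genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone). The chaperone Hspa5 went from 19.5 ± 0.386 to 27.7 ± 0.0781 RPKM, and the small heat shock gene Hspb7 from 121 ± 26.1 to 54.8 ± 17.6. That set passed as higher than the other tested genes (adjusted p = 0.0216 with camera), but its median log2 fold change was 0.02, with 12 members above 0 and 10 below. It did not pass with an estimated correlation (adjusted p = 0.917), equal library medians (adjusted p = 0.117) or totals without the 10 most abundant genes (adjusted p = 0.0779). Nor did it pass without WT replicate 3 or 4 or KO replicate 2 (adjusted p of up to 0.0806), or with replicate number as a block (adjusted p = 0.136). Hspb7 lost its call without KO replicate 1 or 3 (adjusted p of up to 0.0578).

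Markers of other cell types did not move together. Of 5 tested nerve and Schwann cell markers 4 fell (4 adjusted over the list alone), among them the myelin genes Pmp22, from 11.1 ± 2.53 to 2.70 ± 0.504 RPKM (log2 fold change -1.70, SE 0.16, adjusted p = 0.00136), Prx (-1.14) and Mbp (-0.74). Cnp was at -0.18 (adjusted p = 0.174). The set passed as lower (adjusted p = 0.000365) and by fry's directional test (adjusted p = 0.0243), but not with an estimated correlation in camera (adjusted p = 0.898). Of 16 extracellular matrix genes 4 rose and 1 fell (4 and 1 adjusted over the list alone). The collagen gene Col6a2 went from 1.22 ± 0.34 to 2.39 ± 0.5 RPKM, and the matricellular gene Ctgf from 4.18 ± 1.14 to 1.78 ± 0.386. Of 7 markers of fibro-adipogenic progenitors, the matrix-forming stromal cells of muscle, 1 rose, Smoc2 (3 adjusted over the list alone). Both sets passed as higher (adjusted p = 0.000463 and 0.00188), but not with an estimated correlation (adjusted p = 0.917 for each). Col6a2 lost its call without WT replicate 3 or KO replicate 1 or 2 (adjusted p of up to 0.0722) and Smoc2 without WT replicate 3 or 4 or any KO replicate (up to 0.137).

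Of 13 endothelial markers 2 fell (2 adjusted over the list alone; set adjusted p = 0.441), among them the tight junction gene Cldn5, from 2.57 ± 1 to 0.711 ± 0.0275 RPKM. None of 9 smooth muscle and pericyte markers passed in limma, over the list alone or over all genes, with 1 lower at an unadjusted p under 0.05 (set adjusted p = 0.782). Too few members for a set test were measured of the adipocyte (4), macrophage (4), red blood cell (4), tenocyte (2), lymphocyte (1) and neutrophil and mast cell (0) lists. Among these, Car3 and Fabp4 of the adipocyte list, genes that muscle or endothelium also express, fell (log2 fold changes -0.89 and -0.56; 1 higher and 2 lower adjusted over the list alone), and the immunoglobulin heavy chain Ighm rose from 5.52 ± 3.4 to 17.1 ± 4.56 RPKM (1 adjusted over the list alone). None of the macrophage, red blood cell or tenocyte genes passed in limma, over the list alone or over all genes, with 1, 0 and 0 higher at an unadjusted p under 0.05. Fabp4 lost its call without KO replicate 3 (adjusted p = 0.0681) and Ighm without KO replicate 1 or 3 (up to 0.0756).

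Clock genes changed singly. Of 16 tested circadian genes 2 rose and 4 fell (4 and 4 adjusted over the list alone), and the set did not pass (adjusted p = 0.782). The repressor Bhlhe40 went from 4.82 ± 0.441 to 2.45 ± 0.547 RPKM and the nuclear receptor Nr1d1 from 9.27 ± 0.833 to 6.02 ± 0.389. Of 9 immediate early genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; set adjusted p = 0.655), with Jun lower at -0.66 and Nr4a1 higher at 0.69. Of 20 genes of IGF, PI3K, AKT and mTOR signalling 2 rose and 2 fell (2 and 2 adjusted over the list alone; set adjusted p = 0.975), among them Igfbp5, from 10.6 ± 3.93 to 25.2 ± 2.08 RPKM. Of 11 myogenic and satellite cell genes 4 fell (4 adjusted over the list alone; set adjusted p = 0.45), the imprinted non-coding RNA H19 from 671 ± 235 to 322 ± 61.8 RPKM. H19 lost its call without WT replicate 3 or KO replicate 1 or 3 (adjusted p of up to 0.0885).

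Of 7 myokine and growth factor genes, Gdf11 rose from 2.54 ± 0.166 to 5.44 ± 0.505 RPKM and Mstn, the brake on muscle growth, fell (2 and 1 adjusted over the list alone). The set passed as higher (adjusted p = 0.0323), but not with an estimated correlation (adjusted p = 0.84) or equal library medians (adjusted p = 0.146), nor without WT replicate 4 or KO replicate 2 (adjusted p of up to 0.0737). Nor did it pass with no filter on low values (adjusted p = 0.433), in limma-voom (adjusted p = 0.429) or with totals without the 10 most abundant genes (adjusted p = 0.142). Mstn lost its call without WT replicate 2 or 3 or KO replicate 1 or 2 (adjusted p of up to 0.108). None of 36 cytosolic ribosomal protein genes passed in limma, over the list alone or over all genes, and 6 were lower at an unadjusted p under 0.05. The set passed as lower (adjusted p = 0.0327), but not with an estimated correlation (adjusted p = 0.917) or equal library medians (adjusted p = 0.299), nor without WT replicate 3 or 4 or KO replicate 2 (adjusted p of up to 0.53). Nor did it pass with a pseudocount of 0.1 (adjusted p = 0.114), in limma-voom (adjusted p = 0.109) or with totals without the 10 most abundant genes (adjusted p = 0.704). With replicate number as a block the ribosomal set did not pass either (adjusted p = 0.136). Of 24 sarcomere and costamere genes 3 fell (3 adjusted over the list alone; set adjusted p = 0.975), of 6 denervation and neuromuscular junction genes 1 fell (1 rose and 1 fell adjusted over the list alone; set adjusted p = 0.441), and of 5 interferon response genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; set adjusted p = 0.45).

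Beyond the lists, several of the largest changes lay in genes that overlap others or share their sequence. Plac9b went from 2.76 ± 0.829 to 15.9 ± 0.652 RPKM and Gm9780 from 0.842 ± 0.213 to 5.34 ± 0.156, and all 50-base stretches of both also occur in Plac9a, so the share of each is uncertain. The microRNA genes Mir6935 and Gm23419 (log2 fold changes 2.16 and 1.47) lie on the same strand within Actg1, a cytoplasmic actin gene that rose too (1.45, adjusted p = 0.00104), and all their 50-base stretches occur in it. Peg3, an imprinted zinc finger gene, fell from 11.6 ± 4.19 to 2.14 ± 0.337 RPKM, and Atp1b4, a muscle protein of the nuclear membrane, from 7.14 ± 1.03 to 1.64 ± 0.228. The pseudogene Hmgb1-ps8 and the antisense gene Gm26740, which overlap each other on chromosome 10, fell as well (-2.16 and -1.87).

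More reads were counted to 3 adjoining mitochondrial genes in KO (GENCODE M21 annotation of GRCm38), and 2 of the 3 have near-identical nuclear copies among the annotated transcripts. Copies of mt-Tg outside annotated transcripts were not searched for. mt-Tg, the glycine tRNA gene at positions 9391 to 9458, had 2, 0 and 3 reads in the WT libraries and 152, 150 and 121 in the KO libraries, a ratio of 86.5 with a 95% exact interval of 36.8 to 268 that covers counting error only. mt-Nd3, at 9459 to 9806, went from 89.1 ± 16.2 to 171 ± 24.3 RPKM (log2 fold change 0.94, SE 0.15, adjusted p = 0.00721). mt-Co3, at 8607 to 9390, stood at 0.881 ± 0.502 and 1.98 ± 0.256 RPKM, and its call ended without WT replicate 2 or 3 or any KO replicate (adjusted p of up to 0.101). Of 11 tested mitochondrially encoded mRNAs these 2 rose (2 adjusted over the list alone) and the set did not pass (adjusted p = 0.886); its median was -0.23 although the test pointed up. Nearly all 50-base stretches of mt-Nd3 (98%) and mt-Co3 (99.9%) also occur in the nuclear pseudogenes Gm28438 and Gm28437 on chromosome 1. Summed with its copy, mt-Nd3 had 1.04 times the WT reads in KO, scaled to library totals, and mt-Co3 0.784 times, with overlapping groups in both pairs. mt-Co3 held 0.00968 ± 0.00398% of the reads of its pair in WT and 0.0291 ± 0.00442% in KO. On chromosome 1 (24612407 to 24612700) Gm10222, whose stretches all occur in mt-Nd4l, fell from 24.8 ± 11.6 to 1.35 ± 0.382 RPKM (log2 fold change -3.36, SE 0.32, adjusted p = 0.00136). mt-Nd4l held 99.78% of the reads of this pair in WT and 99.985% in KO, and the summed reads of the pair in KO were 0.835 times those in WT.

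**Figure D3:**
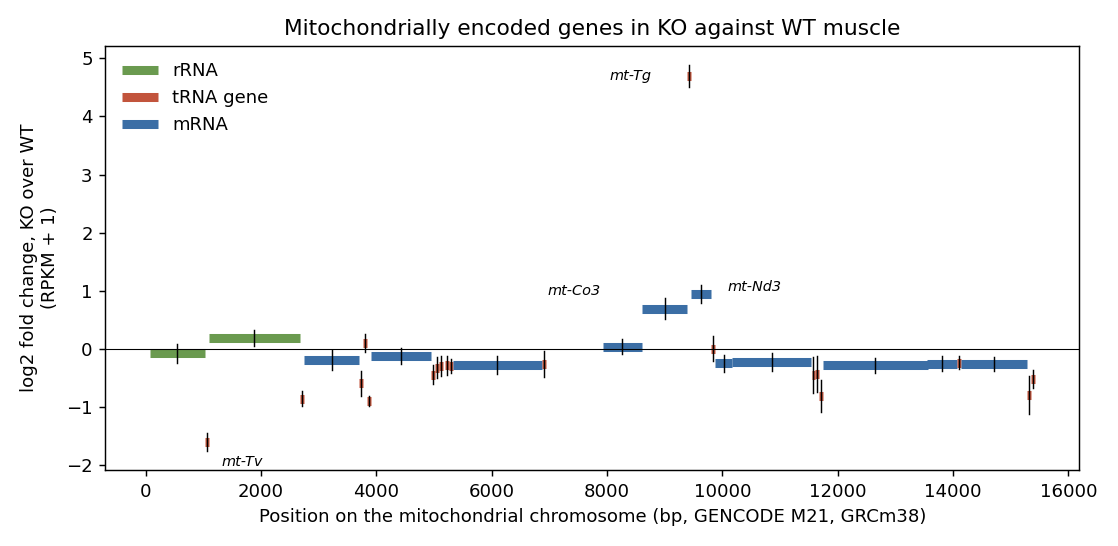
Log2 fold change of RPKM + 1, KO over WT, along the mitochondrial chromosome (bp, GRCm38); coloured bars span each gene and thin lines are standard errors. mt-Tg (4.69), mt-Nd3 (0.94) and mt-Co3 (0.69) stand above the other genes, most of which lie a little below 0, and mt-Tv (-1.60), mt-Tm (-0.91) and mt-Tl1 (-0.86) passed as lower.

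Over all genes, 1311 of 7574 passed adjusted p 0.05 in limma-trend, 290 higher and 1021 lower in KO. In 1310 of the 1311 the 3 KO and 3 WT values did not overlap, and over all tested genes this held for 39.2%, against 10% by chance. With 3 libraries per group a call nearly requires such separation. The 10% holds for a single gene, and an offset shared by a library can separate many genes at once. Neither share is therefore separate evidence of a genotype effect. Myh4 alone took 18.7 to 21.5% of the counted reads in WT and 24.4 to 25.2% in KO, and the median log2 fold change of all tested genes was -0.09. With library medians made equal that median was 0.01, and the calls divided into 602 higher and 665 lower. Of the 1311 calls 409 passed with any single library left out, and without KO replicate 3 the total was 471. Of 28 gene lists 11 passed with the preset correlation of 0.01, and none with an estimated one, where 1 list had an unadjusted p under 0.05. By fry's directional test 1 list passed.

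The authors' deposited table has 191 genes at a false discovery rate under 0.05, 84 higher and 107 lower in KO. Of these, 128 were tested here and 124 were also called, all 124 in the same direction. Most of the 1311 calls here were thus not among the authors' calls, and over all tested genes the sign agreed for 79.3%. Both results come from the same deposited table, so this is no independent check. Among genes named above, Pfkfb3 (FDR 0.176), Fbxo32 (FDR 0.0812) and Pmp22 (FDR 0.103) did not pass there. Gpd1 (FDR 0.0183) and Ppp1r3c (FDR 0.0391) did. In the authors' deposited table Myh1 has a log2 fold change of -0.71 (FDR 0.119), Myh4 of 0.38 (FDR 0.0867) and Ppargc1a of 1.13 (FDR 0.0495). The deposited log2 fold changes could not all be derived from the deposited values. Among 8980 genes with at least 100 reads in every library, 304 had a fold change in the authors' deposited table outside the range of all pairs of KO and WT libraries, after an offset of 0.13.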

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

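limma-voom, totals without the most abundant genes and the restriction to protein-coding genes were chosen after the data were seen. Against 1311 calls (290 higher, 1021 lower), a log2 fold change of at least 1 left 109 (27 and 82), because it adds a condition, and an unadjusted p gave 2532 (575 genes higher in KO and 1957 genes lower in KO), because it drops one. limma-voom on the recovered reads, which tested 11783 genes, gave 2002 calls with 1602 lower. Equal library medians gave 602 higher and 665 lower, and totals without the 10 most abundant genes 683 and 600. Leaving out each library gave 471 to 1637 calls, 117 to 344 higher and 354 to 1293 lower, with fewer libraries in each fit; no called gene changed sign. The number of gene lists that passed, 11 in the main fit, was 0 with an estimated correlation, 1 with fry, 6 with equal medians and 7 with limma-voom. It was 5 without the 10 most abundant genes and 7 to 12 with a library left out, and the cause was not tested. Some of these counts include other lists: of the 11 themselves, 6 passed with limma-voom and 7 to 11 with a library left out. Without the 10 most abundant genes the nerve list had under 5 tested members and got no set test. Of the 111 genes the naming rule took, 41 lost their call without KO replicate 3, 36 without KO replicate 1, 8 with equal medians and 1 with limma-voom, and none of those called changed sign. Of those not called, Myh7 and Ddx3y did, reaching log2 fold changes of 0.57 and 0.02 without WT replicate 2. Whole reads were not recovered for Fbxo32, Ankrd2, Cyr61 and 8430408G22Rik, so limma-voom did not test these members of the 111. The pseudocount of 0.1 (1323 calls), no filter (1847) and protein-coding genes (1186) stayed within 1.5 times. The authors' deposited table has 191 calls, against 1311 recomputed from the deposited RPKM values, from which its fold changes could not all be derived; the cause was not tested. Replicate number as a block gave 1548 calls, 1064 of them among the 1311, and 8 lists, and 3 of the 111 genes lost their call. That fit compares genotypes only within numbers 2 and 3, since KO replicate 1 and WT replicate 4 have no partner. It left 1 residual degree of freedom, against 4 in the main fit, so its count is a weak check. The labels link no libraries and only numbers 2 and 3 are shared, so whether the numbers mark pairs stays open: across genes, deviations from the group mean correlated at 0.479 between WT and KO for number 2 and 0.27 for number 3, and at 0.431 between WT replicate 4 and KO replicate 1. Alternatives planned for a deposited count table (DESeq2, edgeR scalings and count filters) were not run on the recovered reads. With the block the lists of complexes II to V, heat shock and ribosomal proteins did not pass (adjusted p = 0.401, 0.136 and 0.136). Depth limits the genes with few reads, such as mt-Tg with 5 WT reads in all.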

Other observations

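The tests of mitochondrial reads, scaling, abundant genes and splits were chosen after the results were seen; the test of further Schwann cell genes was written before their values were seen. Some changes outside the named-gene rule were chosen after their values were seen. Nnt, the mitochondrial transhydrogenase, stood at 8.79, 5.31 and 5.87 RPKM in the WT libraries and 0.90, 3.25 and 2.55 in the KO libraries. Wdfy1 stood at 1.27, 1.11 and 1.09 RPKM against 0.38, 0.38 and 0.39. The cytoplasmic actin gene Actg1 stood at 17.9, 12.9 and 17.6 RPKM against 46.1, 44.3 and 45.8. Fewer reads, scaled to library totals, were counted to the mitochondrial tRNA genes mt-Tv, mt-Tm and mt-Tl1 in KO, with log2 fold changes of -1.60, -0.91 and -0.86. Reads shared with adjoining genes or with copies elsewhere were not examined for these tRNA genes.

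The higher counts of mt-Co3, mt-Tg and mt-Nd3 were not part of a general rise of mitochondrial RNA, since the other 9 mitochondrially encoded mRNAs had a median log2 fold change of -0.25. For mt-Tg they were not a matter of scaling alone either, since it kept an adjusted p of 1.796e-05 with equal library medians. Its adjusted p was at most 0.000917 with any library left out, a check that does not bear on scaling. Reads passing between near-identical copies may account for mt-Nd3 and mt-Co3 and stay open for mt-Tg. With Gm28438 the summed reads of mt-Nd3, scaled to library totals, had a ratio of 1.04 with overlapping groups, while mt-Nd3 took 29.0 to 30.8% of them in WT and 50.8 to 59.4% in KO. With Gm28437 the summed reads of mt-Co3 had a ratio of 0.784, also with overlapping groups. Of these mt-Co3 took 0.0054 to 0.0133% in WT and 0.0246 to 0.0334% in KO. A first test, which summed the 3 genes with Gm10222 (ratio 1.63), decides nothing, because Gm10222 matches mt-Nd4l. A substrain or maternal line that differs between the groups cannot be told apart from an effect of lnc-ORA, since the breeding of the groups is not in the labels. Nnt, which differs between C57BL/6 substrains, had a log2 fold change of -1.30, with every KO value below every WT value. Of the 3 KO values 1 lay below the 1.77 RPKM that the test asked of all 3, so the test did not decide either way.

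The highest adjusted p of Pmp22, Prx and Mbp was 0.0148 with any library left out and 0.007941 with equal library medians. By the latter value, the fall of nerve and Schwann cell markers, these 3 among them, was not a matter of scaling alone. Less nerve tissue in the KO samples may account for it: of 20 further Schwann cell genes 14 were in the table, 13 of them lower, with a median log2 ratio of mean RPKM of -1.48, from -2.30 for Pllp to 0.07 for Aspa. Only 3 of the 14 passed the filter on low values, Mal, Cadm4 and Art3, with log2 ratios of -1.95, -1.95 and -0.28; on the fitted scale, where 1 is added to each RPKM value, they were at -1.05, -0.85 and -0.26, a median short of the -1 that the test asked for. The other 11 lay below that filter, with as few as 10 reads in a library; in 12 of the 14 every KO value was below every WT value. A change in the nerve or its Schwann cells with genotype was not tested and stays open.

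The excess of lower calls was gone with totals taken without the 10 most abundant genes, where 46.8% of calls were lower. Those genes took 44.4 to 48.3% of reads in WT and 50.2 to 53.9% in KO. Leaving them out therefore raises KO values against WT values, and fewer lower calls had to follow. Equal library medians gave a similar balance, 602 higher and 665 lower. The test cannot tell a few abundant genes from another offset between the groups. The authors' deposited table has 84 calls higher and 107 lower at a false discovery rate under 0.05. The median log2 fold change over all its genes is -0.0043, but the scaling behind it is not given. Which scaling is right for this muscle was not tested.

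The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split gave 1311 calls in limma and the highest of the others 0 (2532 and at most 749 at an unadjusted p under 0.05), with 1 split as large for all, higher and lower calls alike. For gene lists the real split gave 11 and the highest of the others 13, and 3 splits, the real split included, gave at least 11.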
